A study of Aplysia californica with 24 samples.

How the data were processed

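RNA from pleural ganglia of the sea slug Aplysia californica was measured on 24 two-colour oligonucleotide arrays, 8 for each of 3 phases of memory named New, Forgotten and Savings. On each array the trained side of the body was set against the untrained side of the same animals, and each RNA sample pooled 2 animals that had been trained on opposite sides, per the labels' protocols. The arrays lay on 3 slides of 8 arrays, and each phase had 4 arrays with the trained side in Cy5 and 4 with it in Cy3. Labels disagree on this point: the source and phase labels of the channels give these dye swaps, the series' design text states that dye swaps were balanced within each condition, and a separate sensitization label reads Cy5 as trained on all arrays. The source and phase labels were followed, and the other reading was kept as an alternative. Replicates were separate pools of animals, per the series' design text.

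The deposited scanner files hold spot intensity values in the red and green channels, extracted with Feature Extraction 12.1.0.3, per the file headers. The same files give a log10 ratio of red over green, made by that program per the file headers, and it was used here only to find the scale of the deposited value table. That table holds log2 ratios of red over green from the authors, not turned for dye swaps, with array medians between -0.00954 and -9.87e-05, and the submitters' processing notes name limma without a version. On spots well above background in both channels, its columns correlated with the scanner's log2 ratios at r = 0.772 to 0.920. The slopes on the scanner's ratios were 0.458 to 0.642, below 1. With the log2 ratios computed here, its columns correlated at r = 0.999987 to 0.999998. The authors' background and normalization settings are not given in the sources used here.

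Median foreground and median background intensities were used in place of the mean foreground that had been planned, a change made once the columns of the files were known. Background was corrected with normexp and an offset of 50, ratios were normalized within each array by loess with control spots given no weight, control spots were then removed, and 152 values with an outlier flag were left out. Spots of 1 probe were averaged, which gave 61615 probes for 26091 transcript identifiers. A probe was tested when at least 1 channel was well above background on at least 8 arrays, which left 46707 probes of 21273 transcript identifiers. No spot was saturated. The share of spots well above background was 59.4 to 70.2% in green and 69.3 to 75.5% in red, and the number of arrays limits the precision. The slope of observed against expected log ratios of the spike-in controls was 0.744 to 0.845, below 1, per the file headers. It was not computed for the ratios used here.

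The model was fitted with limma 3.58.1 in R 4.3.3 to all 24 arrays, with 1 coefficient per phase, signed by dye orientation, and a common dye term. Tests were moderated by eBayes (prior degrees of freedom 3.78), and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. Each probe had 1 residual spread shared by all phases, so these p-values do not rest on the SD printed for a single phase. The phases have their own untrained tissue, so no control was shared between them. A profile score per array was the mean trained over untrained log2 ratio of the probes that rose in New minus that of the probes that fell, divided by 2, with the dye term removed. New arrays were scored with a list and a dye term from the other arrays. Mean scores were tested with exact two-sided sign-flip permutation, where 8 arrays cannot give a p below 0.00781, and differences with exact two-sided permutation of phase labels. 95% intervals were found by inverting the sign-flip test. Simulated arrays had independent noise of each probe's own spread. Each phase held planted log2 changes of 0.25, 0.5 and 1 together, each in 200 of 46707 probes. A change of 0.5 was recovered in 89.0% of cases for New, 92.0% for Forgotten and 88.0% for Savings. For a log2 change of 0.25 these shares were 47.5%, 53.5% and 44.0%. The adjusted threshold depends on how many probes change, so these shares do not carry over to a phase with fewer changed probes. A probe's simulated spread was the same in all phases, so the shares differ between phases only by the random draw. On the real arrays the median SD of a probe was 0.164 in New, 0.183 in Forgotten and 0.186 in Savings. Noise shared between probes was not simulated, so the shares do not give the sensitivity on the real arrays.

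The arrays identify most probes by the accession of an expressed sequence. Only 2 transcript identifiers, with 4 probes, matched the table of gene symbols for assembly AplCal3.0, and 3 more carried a name in the files themselves, which left 61602 probes unnamed. Of 20 gene lists fixed in advance, 1 matched any tested probe, with 3 probes, under the minimum of 5, so no list was tested. Lists were matched by patterns in the name, which entries with abbreviated names such as ACN4PKA and apnalcn did not meet. Named probes were to be those past the threshold with the same sign on at least 7 of 8 arrays, 12 each way, restricted to probes with a gene name, together with a set of memory genes. None of these was matched to a probe. Therefore at most 2 unnamed identifiers each way were printed for a comparison, those with the largest change under the same rule, taking the brightest probe of a transcript. For Forgotten pooled with Savings, the requirement of the same sign was not applied. The dye orientation check, the alternatives for background, normalization, dim probes, dye, slide, replicate number, array weights, variance model, threshold and channel labels, and the removal of each array in turn were chosen before the data were examined. Scoring New arrays from lists made without them, the score differences of New from the other phases, averaging the probes of a transcript, leaving out arrays of wide spread and pooling Forgotten with Savings were chosen afterwards. Python 3.11.15 drew the plots.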

Results

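Gene expression in the pleural ganglia, which hold sensory neurons of the withdrawal reflexes, was compared between the trained and the untrained side of Aplysia at 3 phases of memory for long-term sensitization. Training was 4 rounds of 90 mA shock to one side of the body at intervals of 30 min. New tissue was taken 1 day after training. Forgotten and Savings tissue was taken 8 days after training, and Savings animals had received a 20 mA reminder 7 days after training. Forgotten animals had received a sham reminder, whose setting is not given in the sources used here. Each phase had 8 arrays, each a direct trained over untrained comparison in pools of 2 animals. The median spot intensity per array was 68 to 104 in green and 51 to 77 in red, over backgrounds of 26 to 32 and 18 to 20. The standard deviation of an array's log2 ratios ranged from 0.193 to 0.416.

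The first comparison asked which transcripts differ between the sides 1 day after training. In New, 1798 of 46707 probes changed, of which 1214 rose on the trained side and 584 fell (limma, Benjamini-Hochberg). The probes that rose belonged to 679 transcript identifiers and those that fell to 370. The median log2 ratio was 0.33 among probes that rose and -0.27 among those that fell, and 34 probes rose and 2 fell by more than 2-fold. At an adjusted p of 0.01, 869 probes changed, with 656 up and 213 down. Transcript EB235892.1 rose 3.03-fold (log2 ratio 1.60 ± 0.45, SD, n = 8, adjusted p = 1.51e-09) and was higher on 8 of 8 arrays. Its other probes gave log2 ratios of 1.54 and 1.56. Its SD was smaller in Forgotten (0.16) and Savings (0.19), and the model shares each probe's spread across phases. GD214292.1 rose 2.79-fold (log2 ratio 1.48 ± 0.58, SD, n = 8, adjusted p = 1.41e-06) on 8 of 8 arrays, with 1.19 for its second probe. GR212349.1 fell by 1.05 on the log2 scale (± 0.27, SD, n = 8, adjusted p = 2.33e-07), and its other probes fell by 0.99 and 1.02. EB238672.1 fell by 0.77 on the log2 scale (± 0.24, SD, n = 8, adjusted p = 3.41e-06), and its other probes fell by 0.61 and 0.63. The deposited files and the gene table do not pair these identifiers with gene names.

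Where a called probe had another tested probe of the same transcript, the others' mean had the same sign for 1167 of 1175 probes that rose and 569 of 571 that fell. These other probes read the same RNA on the same arrays, so their signs are no separate check on a chance difference between the sides. The New count was 1665 with slide as a block and 1526 with each phase fitted alone. Within a single slide of 8 arrays, 10, 76 and 0 probes passed, while 99.8 to 100% of the 1798 probes kept their sign, a description of probes partly chosen on those arrays. The count was 4265 with array weights, 419 with median centring, 1141 without the dye term and 318 against a minimum change of 1.1-fold.

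A few tested probes carried a name. The probe set named apnalcn gave log2 ratios of -0.01 to 0.01 in New (limma, adjusted p = 0.92 to 0.955). Its probes were well above background in at least 1 channel on 9 to 11 of the 24 arrays, and in both channels on 2 or 3. Ratios this close to background say little about its expression. The 3 probes of a neuropeptide precursor gave log2 ratios of 0.03, 0.07 and 0.12 in New, and adjusted p was 0.96, 0.802 and 0.704. Those of the entry named ACN4PKA gave 0.00, -0.01 and -0.06, with adjusted p of 0.997, 0.959 and 0.841. The gene dar1 gave 0.02 (adjusted p = 0.933) and LOC100861465 gave 0.03 and 0.11 (adjusted p = 0.935 and 0.256). None of these passed the threshold in Forgotten or Savings either. They were chosen after the data were seen, because they were the probes with a name.

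The second comparison asked which transcripts still differ between the sides when the memory is no longer expressed. In Forgotten, 0 of 46707 probes passed (limma, smallest adjusted p = 0.306), while 4894 had an unadjusted p under 0.05 against 2335 expected by chance on average. Probes are not independent, and 13 of 100 sets of array signs, the real one included, gave as many, so chance cannot be excluded. The third comparison asked what differs after a reminder. In Savings, 0 probes passed (limma, smallest adjusted p = 0.418), with 2488 at an unadjusted p under 0.05. EB235892.1 had log2 ratios of 0.01 ± 0.16 in Forgotten and -0.10 ± 0.19 in Savings (SD, n = 8), and GR212349.1 had -0.06 ± 0.30 and 0.10 ± 0.28. GD214292.1 had 0.09 ± 0.31 in Forgotten and 0.05 ± 0.46 in Savings. EB238672.1 had 0.03 ± 0.29 in Forgotten and -0.25 ± 0.21 in Savings, where it was lower on 7 of 8 arrays without passing the threshold (adjusted p = 0.892). Without Forgotten replicate 5, 5 probes passed in Forgotten, and without Savings replicate 7, 2 passed in Savings. With slide as a block, 1 probe passed in Savings and 0 in Forgotten.

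Differences between phases were tested directly. New differed from Forgotten at 602 probes, with 423 higher and 179 lower in New, and from Savings at 459 probes, with 341 higher and 118 lower. Of the 1798 probes changed in New, 542 differed from Forgotten, 430 from Savings and 277 from both. For EB235892.1 the difference was 1.59 ± 0.14 from Forgotten and 1.70 ± 0.14 from Savings on the log2 scale (standard error, adjusted p = 3.04e-06 and 5.58e-07). Savings differed from Forgotten at 0 probes (limma, smallest adjusted p = 0.143), with 3685 at an unadjusted p under 0.05. With slide as a block, the counts were 439 for Forgotten and 417 for Savings, and within a single slide they were 0. Counts against Forgotten and Savings were 65 and 61 with median centring and 107 and 97 against a minimum change of 1.1-fold. With array weights they were 1490 and 1040. Leaving out New replicate 8 gave 986 probes for New against Forgotten, and leaving out New replicate 6, New replicate 2 or Forgotten replicate 1 gave 382, 385 and 384. For New against Savings, the count was 300 without New replicate 2.

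The New profile, taken over all 1798 probes, was then followed in the other phases. Left-out New arrays had a mean score of 0.304 ± 0.103 (SD, n = 8), from 0.0915 to 0.382. The mean score was 0.00382 ± 0.0318 in Forgotten (SD, n = 8, 95% interval -0.0230 to 0.0321, exact sign-flip permutation p = 0.719) and 0.0138 ± 0.0349 in Savings (SD, n = 8, 95% interval -0.0165 to 0.0449, exact p = 0.297). New exceeded Forgotten by 0.30 and Savings by 0.29, each at the smallest p that the exact permutation of phase labels allows, 0.000155 (adjusted p = 0.000466 over 6 tests). The permutations kept the scores fixed, and New arrays were scored from left-out lists of 1232 to 1966 probes, the others from all 1798. These 2 p-values are therefore approximate. Savings and Forgotten differed by 0.00997 (exact permutation p = 0.555, adjusted p = 0.666). Adjusted over the same 6 tests, exact p was 0.719 for Forgotten and 0.445 for Savings. On slides 1, 2 and 3 the mean score was 0.281, 0.361 and 0.262 in New, -0.0298, 0.0322 and 0.0185 in Forgotten, and -0.00917, 0.0449 and 0.00154 in Savings.

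**Figure D1:**
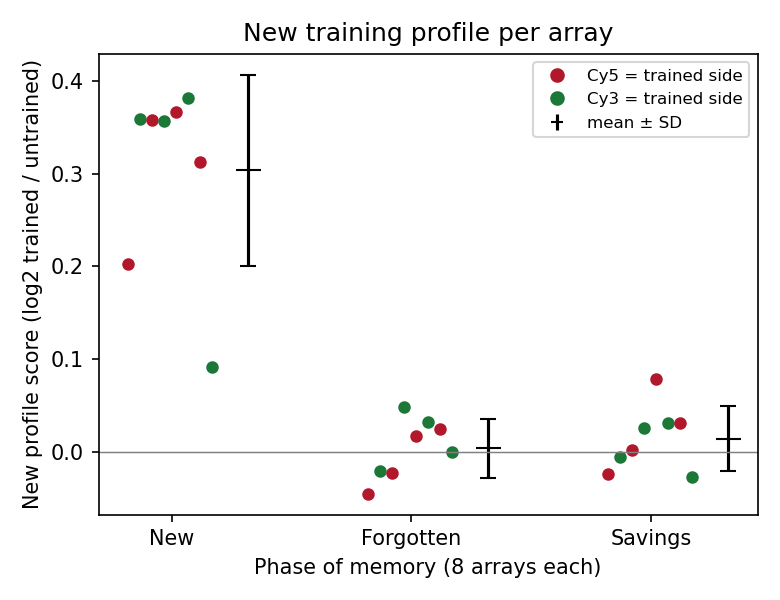
New profile score of each array (mean log2 trained over untrained ratio of probes that rose in New minus those that fell, divided by 2), by phase, with New arrays scored from lists made without them; points are arrays coloured by the dye of the trained side, and bars are the mean ± SD. The 8 New arrays lie between 0.0915 and 0.382, and no Forgotten or Savings array exceeds 0.0781.

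The 100 probes with the smallest p in Forgotten, used because fewer than 10 passed the threshold, had a mean score of 0.0432 ± 0.0982 in Savings (SD, n = 8, 95% interval -0.0330 to 0.126, exact sign-flip permutation p = 0.258, adjusted p = 0.445). This mean was 0.00343 without Forgotten replicate 5, 0.0119 without Savings replicate 4, 0.0266 without Forgotten replicate 3 and 0.0785 without Savings replicate 8. Across all probes, which are not independent replicates, log2 ratios correlated at r = 0.0482 between New and Forgotten, 0.107 between New and Savings and -0.00586 between Forgotten and Savings. As a check of the channel labels, the difference between New and the mean of the other phases was computed separately from arrays with Cy5-trained and Cy3-trained tissue. The 2 sets correlated at r = 0.288 across probes with the swaps of the source labels, with a jackknife standard error over arrays of 0.135. This r was 0.146 with Agilent's processed signals and 0.167 with background subtraction. It was 0.347 for probes with both channels above background on all 24 arrays. The other reading turns the sign of r by construction and is no separate check.

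**Figure D2:**
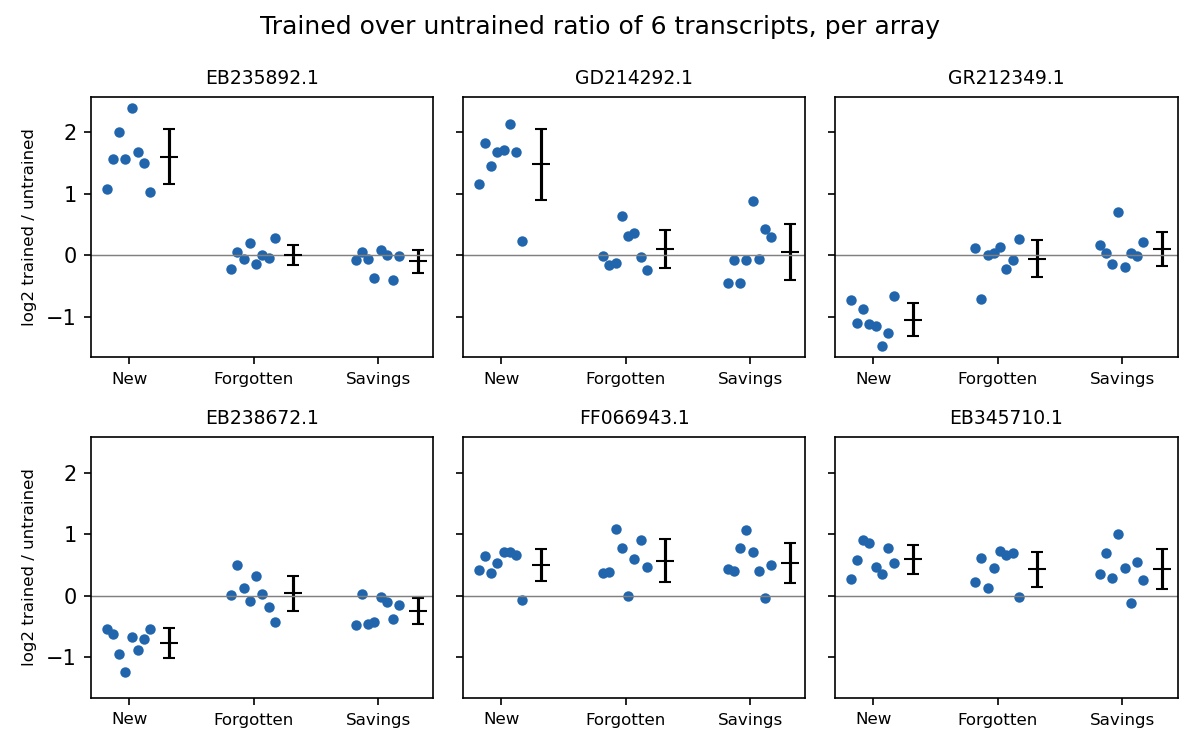
Log2 trained over untrained ratio, dye term removed, of 6 transcripts on each array, by phase; points are the 8 arrays of a phase and bars are the mean ± SD. EB235892.1 averages 1.60 in New and 0.01 in Forgotten, while FF066943.1 averages 0.50 in New, 0.57 in Forgotten and 0.53 in Savings.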

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

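The tests of the New profile against noise, channel swaps and slides, and the choice of transcripts pooled over Forgotten and Savings, came after the results were seen.

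New differed from Forgotten at 602 probes and from Savings at 459, which was a tested difference between groups, and the profile scores differed by 0.30 and 0.29. The mean New profile score was near 0 in both other phases. Of the 1798 probes, 51.6% kept their sign in Forgotten and 58.7% in Savings. At an unadjusted p under 0.05 (limma), 120 kept and 68 turned their sign in Forgotten, and 99 and 49 did in Savings. Probes are not independent, and these shares were not tested. Of 100 sets of array signs in New, the real one included, 1 gave as many as the 1798 probes. This argues against chance, at a share that cannot fall below 1 of 100. The highest other set gave 1202, but it turned 1 array and kept the other New signs. Of 100 splits of the arrays of New and Forgotten, 1 gave as many as 602, with 9 as the highest other, and for New and Savings 1 gave as many as 459, with 0 as the highest other. If Forgotten or Savings held a profile of the New size, swapped channels on some arrays would leave scores of that size with a turned sign. The lowest score among those arrays was -0.0454 and the largest absolute score 0.0781, below the lowest left-out New array at 0.0915. This argues only against a swapped profile of the New size. A smaller profile swapped on some arrays would give small scores of both signs, which this test cannot tell apart. Array noise hiding a profile of the New size is argued against by the upper 95% limits of the mean scores, of which the higher was 0.0449 against a New mean of 0.304. Slide differences are argued against because on each slide every New score exceeded every other, with a smallest gap of 0.0596. The phases differ in time since training, 1 against 8 days, so the loss of the profile may reflect time as well as memory, which the design does not separate between New and Forgotten.

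In Forgotten, 4894 probes had an unadjusted p under 0.05, and 13 of 100 sets of array signs gave as many, with 6622 as the highest other, so chance cannot be excluded. In Savings the number was 2488, reached by 55 of 100 with 6999 as the highest other. For Savings against Forgotten it was 3685, reached by 27 of 100 splits with 9057 as the highest other.

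A total of 31 groups of 8 arrays were examined for an array far from the others, and chance marks about 1 in 20. In 3 an array stood apart. New replicate 8 had a log2 ratio of -0.0698 for FF066943.1, against 0.371 for the nearest array. Savings replicate 4 had 0.698 for GR212349.1, against 0.216. Savings replicate 7 had 59.4% of spots well above background in green, against 66.1% for the nearest.

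Synthetic control spots, which no comparison used, were above background at a median of 11.8% per array, while negative control spots reached at most 3.25%.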

How the results depend on the processing

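Averaging the probes of a transcript and leaving out 3 arrays of widest ratio spread were chosen after the data were seen. These arrays were Forgotten replicate 2 and Savings replicates 4 and 7 (SD of log2 ratios 0.416, 0.410 and 0.400), and none was a New array. Counts are of probes past an adjusted p of 0.05, and a cause was not tested unless the alternative's construction shows it. The New count of 1798 stayed within 1.5 times under 14 of 20 alternatives. These include Aquantile normalization between arrays, which leaves the ratios as they are, and the reading of all arrays as Cy5 trained, which gave 1473 probes but log2 ratios of 0.08 for EB235892.1 and 0.00 for GD214292.1. It was 419 with median centring in place of loess, 1141 without a dye term, 4265 with array weights, 318 against a minimum change of 1.1-fold, 903 with probes averaged per transcript (fewer units tested) and 2825 without the widest arrays. New against Forgotten gave 304 and New against Savings 228 with background subtraction, 361 and 224 with Agilent's processed signals, 65 and 61 with median centring, 298 and 244 without a dye term, 1490 and 1040 with array weights, 107 and 97 against 1.1-fold, and 318 and 244 with probes averaged. The share that rose in New, 67.5%, ranged from 60.8% with array weights to 89.0% against 1.1-fold. The share higher in New than Forgotten, 70.3%, ranged from 63.4% with array weights to 84.6% with median centring and 89.7% against 1.1-fold, and was 61.9% without New replicate 8. Against Savings it was 74.3%, from 68.9% with median centring to 84.4% with processed signals and 92.8% against 1.1-fold. With all arrays read as Cy5 trained, which leaves the dye effect in the ratios, Forgotten gave 3614 and Savings 2516, both differences from New gave 0, the New score was 0.263 in Forgotten and 0.291 in Savings, the Forgotten score in Savings was 0.196, the orientation check was -0.288 by construction, GR212349.1 was 0.230 in New and FF066943.1 was -0.105 pooled. In the other alternatives Forgotten gave 0, and Savings gave 0 except 1 with slide as a block. Processed signals gave a New score of -0.00103 in Forgotten and an orientation r of 0.146, and background subtraction gave an orientation r of 0.167. The New score in Forgotten was 0.0308 with the 100 probes of smallest p (exact sign-flip p = 0.203). It was 0.0182 with a dye term per slide (exact sign-flip p = 0.258). The Savings minus Forgotten score was -0.0194 with the 100 probes of smallest p and -0.00192 without the widest arrays, where the Forgotten score in Savings was -0.00140, all with exact permutation p above 0.5. The deposited value table gave 1797, 603 and 460 for New and its 2 differences. Without each array in turn, New ranged from 1232 to 2097, Forgotten from 0 to 5, Savings from 0 to 2, New against Forgotten from 382 to 986, New against Savings from 300 to 575, the New score from -0.0102 to 0.0229 in Forgotten and from 0.00199 to 0.0210 in Savings, their difference from -0.0192 to 0.0284, the Forgotten score in Savings from 0.00343 to 0.0785 and the orientation r from 0.234 to 0.346. With replicate number as a block, which takes the place of the dye term, New gave 1955, Forgotten 0, Savings 0, the differences from New 689 and 453, Savings against Forgotten 0, the New scores 0.00189, 0.0173 and their difference 0.0154, the Forgotten score in Savings 0.0664 and the orientation r 0.288. Same-numbered arrays of different phases correlated between -0.378 and 0.298 and 3 of 24 correlated best with their own number, so the numbers were not taken as pairs. The tests of gene lists with an estimated correlation were not run, because no list had enough probes, and the differences between phases could not be fitted with each phase alone. Signal over background limits 14908 probes that were not tested.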

Other observations

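After each phase alone gave no probe in Forgotten or Savings, their mean was tested, a contrast chosen after the data were seen. It called 4 probes of 3 transcripts (limma), all higher on the trained side. FF066943.1 had a pooled log2 ratio of 0.55 ± 0.08 (standard error, adjusted p = 0.00776) and was higher on 14 of 16 arrays. Its log2 ratio was 0.50 in New (limma, adjusted p = 0.00649), 0.57 in Forgotten and 0.53 in Savings. It differed in New from Forgotten by -0.07 ± 0.15 and from Savings by -0.03 ± 0.15 (standard error). Its second probe gave 0.52 pooled. In each phase 1 array stood near 0, with the others from 0.360 to 1.08. EB345710.1 had a pooled ratio of 0.43 ± 0.07 (adjusted p = 0.033) and 0.59 in New (adjusted p = 0.00054). The third transcript had 0.39 pooled and -0.02 in New. Of the 4 probes, 3 were also among the 1798 of 46707 changed in New. The New arrays come from other animals, but the fit shares each probe's spread across phases.

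Whether these transcripts stay raised 8 days after training was not decided, and the third was not raised in New. A dye bias of the probe cancels in the pooled mean, which holds as many arrays of one orientation as of the other. The lowest mean of a called probe within an orientation was 0.346 ± 0.065 (standard error). These means had the fitted dye term removed and come from the arrays that called the probes, so they are no separate check on a dye bias. Each called probe was positive on at least 14 of the 16 arrays, but the probes were picked on these same arrays, so this count leaves open whether a few arrays carry the mean. Of 100 sets of array signs, 2 gave as many as 4 probes, with 72 as the highest other, a share that takes no account of the contrast having been chosen after the single phases gave 0 probes, so chance stays open. The count was 2 to 10 without each array in turn, 11 with a dye term per slide, 0 against a minimum change of 1.1-fold, and 7998 with all arrays read as Cy5 trained, which leaves the dye effect in the ratios. EB345710.1 missed the threshold under 7 of 19 alternatives and without 11 of the 24 arrays in turn (highest adjusted p = 0.116), while FF066943.1 missed it with a minimum change of 1.1-fold (adjusted p = 0.308) and when Cy5 was read as trained throughout.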
